A study of Homo sapiens with 288 samples.

How the data were processed

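Myeloma cells from 144 patients were profiled before dexamethasone treatment, each on the A and the B array of the Affymetrix human genome set, which makes 288 arrays. The 2 arrays of a patient were matched by the shared part of their titles. Total RNA was extracted with the RNeasy Mini Kit and biotinylated cRNA was prepared by the Affymetrix protocol, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, and MAS5 is the tool named in the submitters' processing notes; its version is not given in the sources used here. The values themselves showed that the authors had scaled each array to a common level: the mean intensity after trimming 2% at each end lay within 1 unit of 500 on all 144 A arrays and on 142 of the 144 B arrays. The other 2 B arrays lay far below this level and were multiplied by 1 factor each to reach a trimmed mean of 500; the deposited values without this step are an alternative chosen after the data were examined. Scanner images and probe-level intensities were not used here. The depth of an array has no count, so the number of patients and the error of an array limit the precision.

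Values were analysed as log2(intensity + 16). Differences on this scale understate those of weakly expressed genes. Probe sets were named from the platform annotation. On the A array it listed 19071 probe sets with 1 gene and 1043 with several, and 2107 were not listed. On the B array these numbers were 15432, 554 and 6597. Probe sets with several genes or none were left out. Each gene was represented by 1 probe set, the one with the highest mean; the A array took precedence, and probe sets with the suffix _x_at were used only where a gene had no other. This gave 17486 genes. Genes whose median lay in the lowest 25% of their array design were left out, which left 13114 genes, 8954 from the A and 4160 from the B array. Y-linked genes, XIST and TSIX were excluded from all steps. Counts of patients with high expression used all genes, since a filter on the median removes genes that are expressed in few patients. Chromosomes and gene order were taken from the RefSeq table of assembly GRCh38.p14; the array files name no genome build, so no coordinates are given.

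The labels give 1 group of patients, so there was no comparison of groups, and the 144 patients are the replicates of all relations. Arrays of a patient were compared over 100 probe sets present on both designs, with a one-sided permutation test of the median correlation (100000 permutations of patients). Co-variation within 25 gene lists was tested against 10000 random lists of the same size, matched on mean expression in 10 bins and on array design, one-sided. The proliferation score was the mean z-score of 28 cell cycle genes. Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on the proliferation score, or on the level of NR3C1, each in units of 1 SD over patients. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Genes that define a score were left out of its fit. The lists were tested with camera, with its preset correlation and with an estimated one. Relations between scores were tested by two-sided permutation (100000 permutations, or 20000 in the alternatives and for the proliferation score within its components), with 74 relations adjusted together. Where a mixture model placed a score in separate components more than 2 SD apart with at least 6 patients each, relations are given only within components. For ribosomal protein genes and the 8 chromosomes, covariates were partialled out within a component, with 2000 bootstrap samples of patients for the share of rho that remained. Expression of an autosome was the mean z-score of its genes after each patient was centred on the mean over all genes. The mean Spearman correlation among 8 chromosomes was compared with that of all other pairs by an exact one-sided test over all 319770 choices of 8 among 22 autosomes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for all other steps.

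The tests, gene lists, alternatives and rule for named genes were fixed before the data were examined, except where said otherwise. Named genes are the 10 with the largest SD among genes whose median was above that of all genes of their array. For each fit, they are the 10 largest positive and 10 largest negative slopes with adjusted p under 0.05 and a mean above the median of all genes. These genes also had to keep sign and threshold with the measure of RNA integrity as a covariate. Members of the lists and NR3C1 may be named as well. RNA integrity was measured as the mean log2 ratio of the 3 prime to the 5 prime control probe sets for GAPDH and ACTB; its median was 0.27 and 10% of patients lay above 0.82. The alternatives changed the pseudocount (1 or 64), the scaling, the choice of probe sets, the filter, the array designs, the patients and the covariates. The covariates were RNA integrity, the scores of 5 lists of blood cell markers, the proliferation score for the chromosomes and, added later, the level of the spiked-in hybridisation controls.

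The steps were tested on simulated data. In a fit of the same size as that on NR3C1, with 13113 genes, 78% of 100 genes with a slope of 0.25 log2 per SD and 99% of 100 genes with a slope of 0.5 were recovered, and 11 of 12913 unchanged genes were called. The genes of this fit were simulated as independent of each other, so it does not show the rate of false calls among correlated genes. Of 500 random lists, 6.2% had a p-value under 0.05 in the test of co-variation, and of 1000 unrelated scores 6% did so in the permutation test of relations. With gene positions shuffled, the chromosome test gave a p-value under 0.05 in 8 of 100 runs; 20 runs had been planned, and the number was raised after 3 of them fell under 0.05.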

Results

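Gene expression was measured in myeloma cells, the malignant plasma cells of multiple myeloma, from 144 newly diagnosed patients before dexamethasone treatment. Each patient contributed 1 A and 1 B array, and 13114 genes entered the analyses. The title of the series names a model of risk from gene expression. The labels give no outcome or response, so these were not analysed here, and the questions addressed were which genes differed most between patients, which genes varied together and which genes followed proliferation and the glucocorticoid receptor.

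Both arrays of a patient gave similar values. Over 100 probe sets present on both designs, the median Pearson correlation across the 144 patients was 0.705 (quartiles 0.625 and 0.795) and the median Spearman correlation was 0.735. With patients shuffled, the median Pearson correlation reached at most 0.113 (permutation test, p = 1e-05, the smallest it can give). Over these probe sets, the error of 1 array was 0.25 on the log2 scale, a factor of 1.19. In 137 of 144 patients the A array correlated best with the patient's own B array; in 2 patients that correlation was under 0.2.

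Genes differed in their spread between patients, with a median SD of 0.63 log2 over 13114 genes. Among genes with a median above that of all genes, the immunoglobulin heavy chain locus IGH (SD 2.81), LAMP5 (2.77), EDNRB (2.64), S100A4 (2.52) and C11orf96 (2.51) had the largest SDs. They were followed by RGS1 (2.48), CCND2 (2.46), CD9 (2.38), FRZB (2.37) and SULF2 (2.35). EDNRB encodes an endothelin receptor, CD9 a tetraspanin of the cell surface, FRZB a secreted antagonist of Wnt signalling and SULF2 an extracellular sulfatase. The level of LAMP5 at the 95th percentile of patients was 234 times that at the 5th percentile, and for FRZB this ratio was 125. The other probe sets for IGH did not follow the one used here (Spearman rho from -0.20 to 0.38). The 16 plasma cell identity genes had a median SD of 0.77, above that of all genes, and ranged from POU2AF1 (0.42) to CD27 (1.71). Within this list, SDC1, which encodes the plasma cell surface marker CD138, had a median log2 level of 13.58 and an SD of 0.54, and XBP1, a transcription factor of plasma cells, had a median of 13.41 and an SD of 0.47. Interferon response genes had a median SD of 1.07, with IFIT1 at 2.05, and proteasome genes one of 0.48. The SD was more than 2 times the error of an array for 10071 genes (76.8%), and for 4388 with the 2 unscaled B arrays left as deposited, where that error rose to 0.40. The error was measured over the 100 probe sets present on both designs and may not hold for other genes, such as weakly expressed ones. The share of genes passing rose as weak genes entered. It was 67.0% of the 8742 more highly expressed genes and 80.9% of all 17486 genes. With a pseudocount of 64 it was 64.7%, and with 1 it was 79.4%. The count of 10071 sets different patients against the technical error of these 100 probe sets alone. It may include genes with a larger array error. Nor does it show how far patients with myeloma differ beyond other people.

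Several genes of the list named for immunoglobulin translocation targets and D cyclins were expressed at a high level in part of the patients. The D cyclins drive entry into the cell cycle. CCND2 was at least 4-fold above its own median in 60 of 144 patients (41.7%, exact 95% interval 33.5 to 50.2%), CCND1 in 29 (20.1%, 13.9 to 27.6%) and CCND3 in 13 (9.03%, 4.89 to 14.9%). FGFR3, a receptor tyrosine kinase, was high in 13 patients (9.03%, 4.89 to 14.9%). NSD2, a histone methyltransferase and neighbour of FGFR3, was high in 14 (9.72%, 5.42 to 15.8%) and the transcription factor MAF in 18 (12.5%, 7.58 to 19.0%). ITGB7, an integrin in the list that is not itself a known translocation target, was high in 10 (6.94%, 3.38 to 12.4%). No patient had MYC 4-fold above its median, which allows a share of up to 2.53%. The median of MYC was the highest of these genes (11.27 log2), and its 95th percentile was 12.76. The cut lies near the top of its range, so this count does not show how many patients express MYC at a high level. The intervals cover counting error only. The 2 other probe sets for NSD2 correlated with the one used at 0.481 and 0.491. Levels of CCND1, CCND2, FGFR3 and NSD2 fell into separate components, 5.26, 5.31, 5.72 and 4.97 SD apart. Those of MYC fell into 3 components, the closest 2.85 SD apart, and the mixture model did not separate those of MAF and ITGB7 in the same way. CCND3 was fitted with 3 components, the closest 2.68 SD apart. The smallest held fewer than 6 patients, so they did not count as separate. MAF was separated with a pseudocount of 64 (2.55 SD) and with the mean over all probe sets (2.45 SD). With a pseudocount of 1, FGFR3 was fitted with 3 components, the closest 2.00 SD apart, instead of 2. The mean over all probe sets also gave 3 components for FGFR3 (the closest 5.64 SD apart) and CCND1 (3.30 SD). Without 4 patients whose B array was unscaled or correlated under 0.2 with the A array, MYC was fitted with 2 components (3.21 SD).

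High levels of some of these genes occurred in the same patients more often than independent genes would, although the overlaps are counts without a test. FGFR3 and NSD2 were both high in 12 patients, against 1.26 expected for independent genes. All 13 patients with high FGFR3 and all 14 with high NSD2 also had high CCND2, against 5.42 and 5.83 expected; at 3 log2 units above the median 9 of 12 and 6 of 9 did. MAF and ITGB7 were both high in 6 patients (1.25 expected), and 9 of the 10 patients with high ITGB7 had high CCND2 (4.17 expected). CCND1 and CCND2 were both high in 2 patients, against 12.1 expected. At least 1 of the 3 D cyclins was high in 93 of 144 patients, against 83.0 expected, and exactly 1 in 84. The counts of patients depend on the limit chosen. At 3 log2 units above the median they fell to 38 for CCND2, 9 for NSD2, 5 for CCND3 and 10 for MAF. At 1.5 they rose to 23 for CCND3, 29 for MAF, 18 for ITGB7 and 7 for MYC. Those for CCND1 (27 and 35) and FGFR3 (12 and 14) moved less with the limit. With the mean over all probe sets, the count was 18 for FGFR3, 27 for CCND1 and 51 for CCND2. The other probe set for FGFR3 correlated at 0.526 with the one used.

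**Figure D1:**
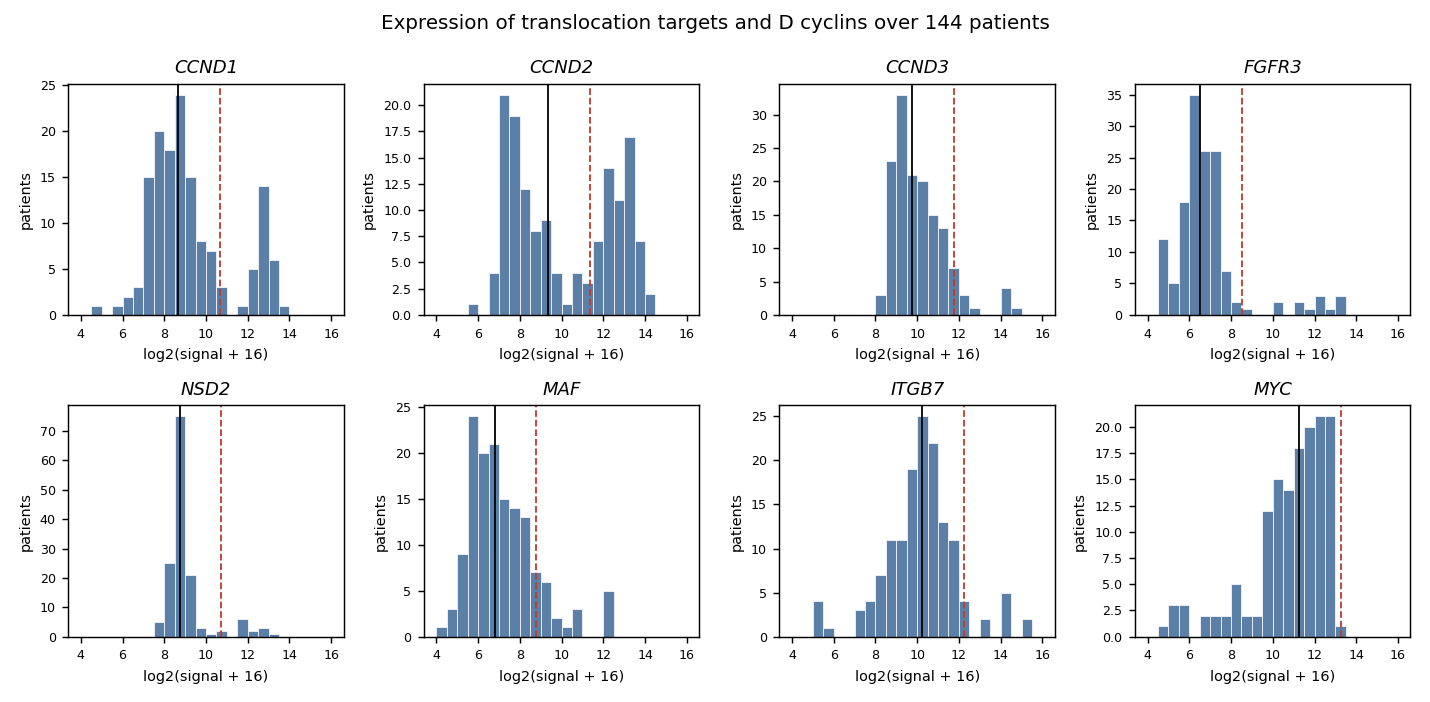
Number of patients (vertical axis) by log2(signal + 16) (horizontal axis, bins of 0.5) for 8 genes in 144 patients; the solid line is the median and the dashed line lies 2 log2 units above it. CCND1 and CCND2 show a second peak beyond the dashed line, with 29 and 60 patients at or above it, and NSD2 has a narrow main peak with 14 patients at or above the line.

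The genes of a list rose and fell together across patients in 20 of 25 lists, which group genes by function, cell type, position or published risk. Ribosomal protein genes had the highest mean pairwise Spearman correlation (0.639 over 20 genes), followed by proliferation genes (0.624 over 28 genes). After quantile normalization this order changed, with 0.321 for ribosomal protein and 0.594 for proliferation genes. Interferon response genes reached 0.469, the 9 genes of 1q21, a region often gained in myeloma, 0.415, and 6 cancer-testis antigens, genes normally expressed in germ cells, 0.407. NF-kappaB targets reached 0.254 and genes of endoplasmic reticulum chaperones and the unfolded protein response 0.284. Proteasome genes were at 0.222, oxidative phosphorylation at 0.185, glycolysis at 0.158 and plasma cell identity genes at 0.0868. Glucocorticoid-responsive genes, such as TSC22D3 and DUSP1, had a mean correlation of 0.110. The published risk genes, taken from earlier work on myeloma, reached 0.147 for the 39 measured high-risk genes and 0.0738 for the 12 low-risk genes. The high-risk genes include ASPM, AURKA and BIRC5 of the proliferation list. Adjusted p-values of these lists ranged from 0.000227, the smallest in the set, to 0.0237 for plasma cell identity.

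Markers of other blood cells also varied together. The mean correlation was 0.485 for the 6 measured monocyte and macrophage markers and 0.470 for the 4 measured platelet and megakaryocyte markers. It was 0.361 for 8 granulocyte and precursor markers and 0.270 for 10 T and NK cell markers. The 7 erythroid markers (0.152) and 10 B cell markers (0.106) passed with adjusted p-values of 0.0233 and 0.027. Quantile normalization lowered the values for T and NK cell (0.136), erythroid (0.0665) and B cell markers (0.0535), which still passed. Glucocorticoid receptor chaperones and cofactors (0.0530, adjusted p = 0.0504), stromal markers (0.139), BCL2 family genes (-0.00131), bone and niche factors (-0.0157) and the translocation targets with the D cyclins (-0.0731) did not pass. The receptor chaperones lie at the threshold: they passed in 7 of 13 alternatives, for example after quantile normalization (adjusted p = 0.0298) and with the mean over all probe sets (adjusted p = 0.00776).

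**Figure D2:**
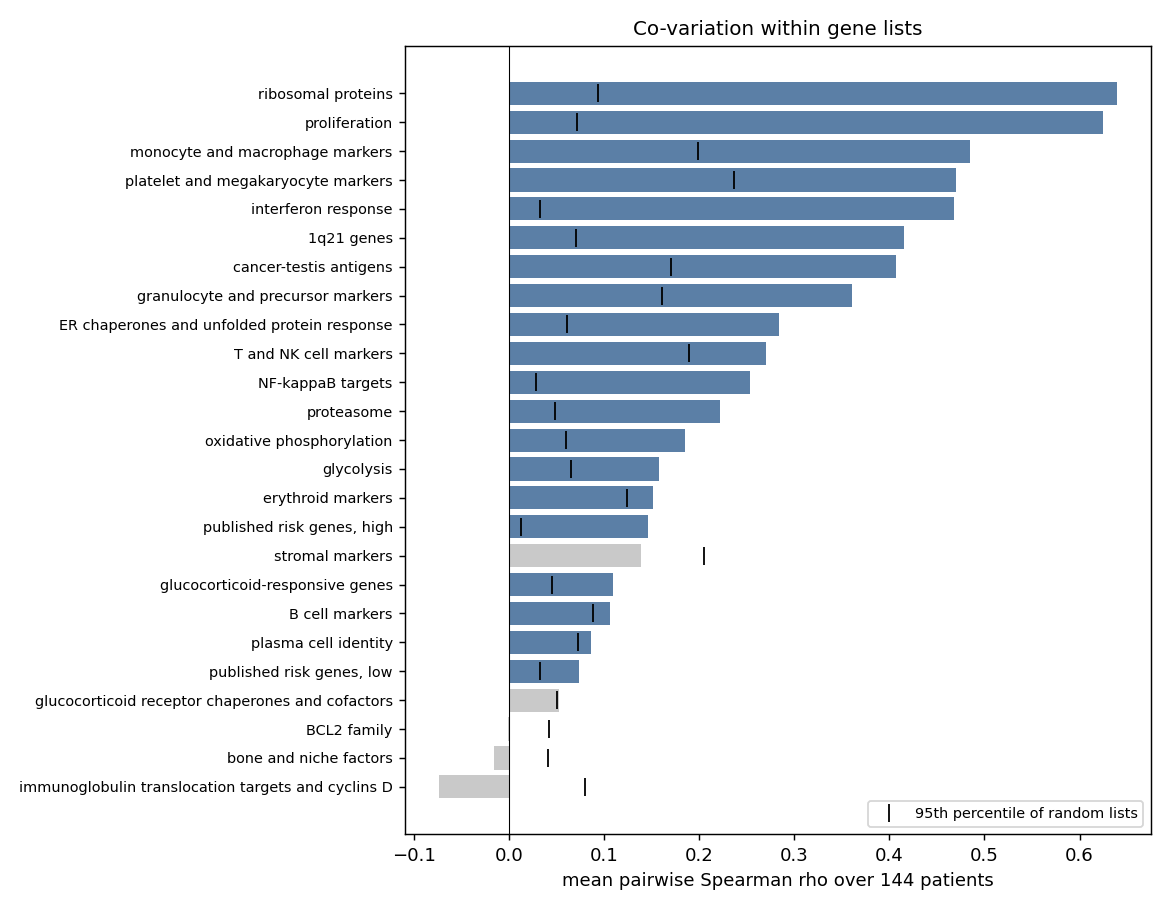
Mean pairwise Spearman correlation across 144 patients (horizontal axis) for the measured members of 25 gene lists; blue bars passed the test at an adjusted p under 0.05, grey bars did not, and black marks give the 95th percentile of 10000 random lists. Ribosomal proteins (0.639) and proliferation genes (0.624) lie far above their random lists.

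Proliferation was followed by a broad set of genes. Of 13086 genes tested, 888 rose and 559 fell with the proliferation score (limma, adjusted p under 0.05). Among genes with a mean above the median, the largest positive slopes belonged to UBE2T, a ubiquitin-conjugating enzyme of DNA repair (1.02 ± 0.08 log2 per SD, SE), PCLAF, a PCNA-binding protein (0.84 ± 0.05), the kinetochore gene CENPW (0.73 ± 0.08), PHF19 of the Polycomb complex (0.73 ± 0.06) and the histone chaperone ASF1B (0.68 ± 0.05). CCND2 (0.67 ± 0.19), GGH (0.61 ± 0.07), ZNF367 (0.60 ± 0.06), SKA3 (0.60 ± 0.09) and MTFR2 (0.57 ± 0.05) completed the list. The largest negative slopes among these more highly expressed genes were those of the protease inhibitor SPINT2 (-0.67 ± 0.15), MFAP3L (-0.61 ± 0.13), KLHL14 (-0.46 ± 0.16), MARCKS (-0.45 ± 0.12) and STAP1 (-0.45 ± 0.12). KLF6 (-0.43 ± 0.15), RASGRP3 (-0.41 ± 0.13), CBX7 (-0.40 ± 0.06), OSBPL10 (-0.39 ± 0.10) and TRIM22 (-0.39 ± 0.11) followed. KLHL14 lost the threshold in 8 of 17 alternatives and KLF6 in 9 of 18. The other probe sets of OSBPL10 and MTFR2 correlated with the ones used here at no more than 0.01 and 0.32.

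All 6 measured cancer-testis antigens rose with proliferation, among them MAGEA6 (0.82 ± 0.13) and SSX3 (0.52 ± 0.09). Of 9 genes of 1q21, 6 rose, including CKS1B, a cofactor of cyclin-dependent kinases (0.56 ± 0.05), ILF2 (0.22 ± 0.04) and ANP32E (0.22 ± 0.04). Of 36 high-risk genes outside the score, 18 rose and none fell, with KIF14 (0.74 ± 0.05) and TRIP13 (0.53 ± 0.04) ahead. CKS1B and PSMD4 are in both this and the 1q21 list. The high-risk list holds cell cycle genes: ASPM, AURKA and BIRC5 belong to the score and were left out, and others such as CKS1B remained. A rise of the high-risk list with the score was therefore in part likely in advance. Adjusted over the list alone, 6 cancer-testis antigens, 7 genes of 1q21 and 21 high-risk genes passed. These 3 lists also stood out from other genes in camera with an estimated correlation (adjusted p = 0.00674, 0.0251 and 1.13e-06). With that correlation, cancer-testis antigens lost the threshold in 4 of 18 alternatives, 1q21 genes in 3 and high-risk genes in 1. Within the lower component of the proliferation score none of the 3 passed (adjusted p = 0.1003, 0.7113 and 0.4396), and the mean slope of 1q21 genes was negative there.

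Other lists passed only with the preset correlation of camera. Of 26 proteasome genes, 8 rose and none fell, for example PSMD14 (0.16 ± 0.04); adjusted over the list alone 13 rose. The p-value was 0.000183 with the preset and the adjusted p = 0.215 with an estimated correlation. Of 20 ribosomal protein genes, 7 fell, for example RPS9 (-0.22 ± 0.05), and adjusted over the list alone 16 fell (adjusted p = 6.95e-09 with the preset and 0.215 with an estimated correlation). Of 13 NF-kappaB targets, 3 fell: CFLAR (-0.26 ± 0.07), TNIP1 (-0.21 ± 0.04) and NFKB1 (-0.10 ± 0.03), and adjusted over the list alone 4 fell (adjusted p = 0.00271 and 0.215). Among 16 plasma cell identity genes, DERL3 fell (-0.26 ± 0.07), and adjusted over the list alone 3 fell (adjusted p = 0.0222 and 0.215).

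The remaining lists did not pass as sets, but single members did. Of 12 low-risk genes, EVI5 (-0.18 ± 0.05), GNG10 (-0.17 ± 0.06) and AHCYL1 (-0.15 ± 0.04) fell, though GNG10 lost the threshold in 11 of 18 alternatives. Of 22 genes of endoplasmic reticulum chaperones and the unfolded protein response, ATF4 (-0.25 ± 0.05), HERPUD1 (-0.17 ± 0.04) and DNAJB9 (-0.15 ± 0.03) fell and 19 did not pass. Of 23 oxidative phosphorylation genes, NDUFB5, COX4I1 and ATP5F1A fell, and of 12 glycolysis genes, TPI1 rose and SLC2A1 fell. Of 11 BCL2 family genes, BCL2 alone passed (-0.24 ± 0.06). Among glucocorticoid-responsive genes ANXA1 (0.62 ± 0.12), SGK1 (0.28 ± 0.09) and BCL2L11 (0.23 ± 0.05) rose and DUSP1 fell (-0.18 ± 0.06). Of the markers of other cells, HBD (0.55 ± 0.12), GATA1 (0.21 ± 0.07) and CD3E (0.21 ± 0.06) rose.

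The proliferation score itself fell into 2 overlapping components of 94 and 50 patients, 2.36 SD apart, so its relations with other scores are given within them, for 24 lists each. The fit with 2 components was little better than with 1: the gain in the Bayesian information criterion was 3.61, against 71.0 for CCND1. The components therefore need not be 2 kinds of patients. In the lower component, cancer-testis antigens rose with proliferation (r = 0.395, permutation p = 5e-05; rho = 0.373, p = 0.00055, adjusted p = 0.0066; r = 0.320 without the 2 patients farthest from the median). Platelet and megakaryocyte markers (r = 0.406, p = 5e-05; rho = 0.412, p = 5e-05, adjusted p = 0.0012; r = 0.386 without those patients) and granulocyte markers (r = 0.306, p = 0.0019; rho = 0.277, p = 0.0059, adjusted p = 0.036; r = 0.279) rose there as well. In the upper component the 1q21 genes (r = 0.518, p = 0.00035; rho = 0.534, p = 0.00015, adjusted p = 0.0018; r = 0.504) and proteasome genes (r = 0.460, p = 0.0007; rho = 0.421, p = 0.0024, adjusted p = 0.019; r = 0.387) rose. Here 5e-05 is the smallest p these permutations can give. High-risk genes rose in both components, with rho = 0.285 (r = 0.310, p = 0.0028; rho p = 0.0057, adjusted p = 0.036; r = 0.228) and rho = 0.629 (r = 0.664; p = 5e-05 for both, adjusted p = 0.0012; r = 0.569). As the high-risk list holds cell cycle genes, its rise was in part likely in advance here too. The differences between components were not tested. Within the components, 199 and 150 genes passed the threshold in place of 1447, 87.4% and 92.6% of the 1447 kept their sign, and the slopes of CCND2 and STAP1 had the opposite sign in the lower one (-0.04 and 0.16, adjusted p = 0.96 and 0.65). The 1447 genes had been chosen over the same patients, so a kept sign was likely in advance.

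**Figure D3:**
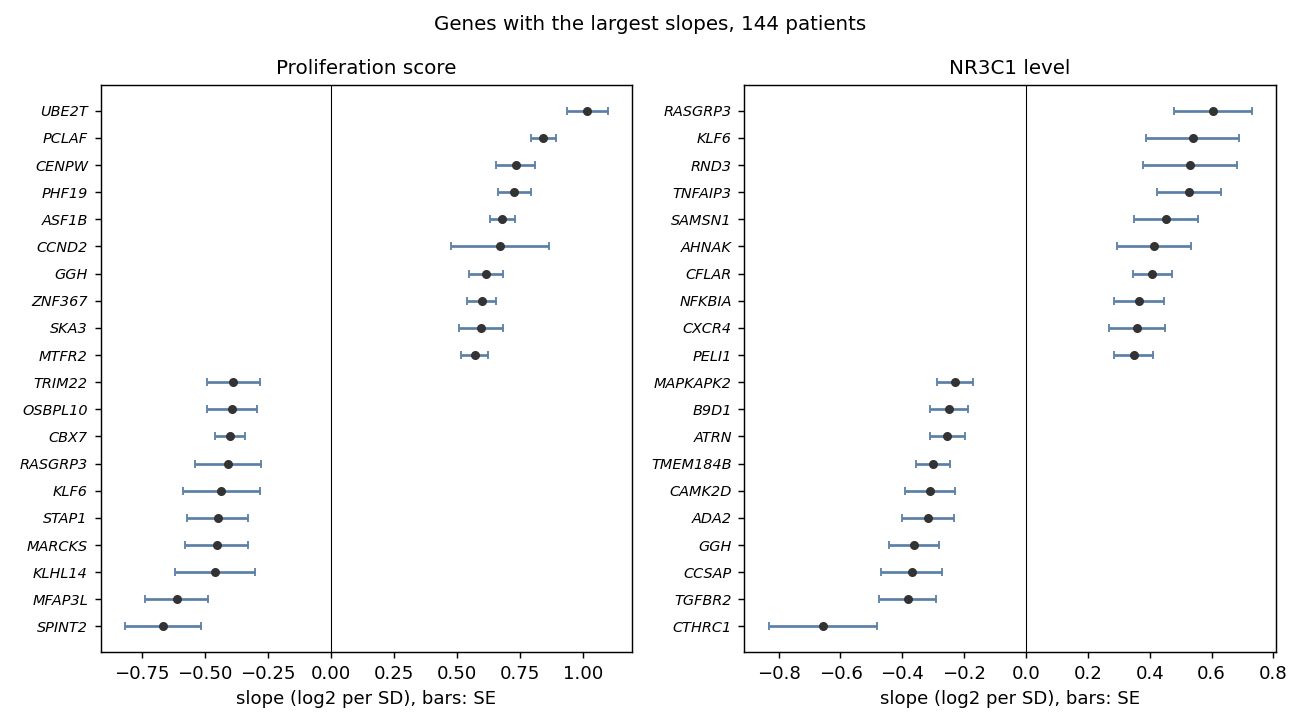
Slopes in log2 units per SD (horizontal axis, points) with their standard errors (bars) for the 10 largest positive and 10 largest negative slopes on the proliferation score (left) and on the NR3C1 level (right), 144 patients. UBE2T has the largest slope on proliferation (1.02), and KLF6, RASGRP3 and GGH have slopes of opposite sign in the 2 panels.

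NR3C1 encodes the receptor for dexamethasone, the drug the patients were about to receive. Its median log2 level was 11.10 with an SD of 0.70, and its level at the 95th percentile was 4.77 times that at the 5th; the 3 other probe sets for the gene correlated with the one used at 0.626 to 0.914. Of 13113 genes, 160 rose and 97 fell with NR3C1 (limma, adjusted p under 0.05); with the mean over all probe sets of a gene, 258 rose and 234 fell. Among genes with a mean above the median, the largest positive slopes were those of RASGRP3, an activator of Ras proteins (0.60 ± 0.13 log2 per SD, SE), KLF6 (0.54 ± 0.15), RND3 (0.53 ± 0.15), TNFAIP3, an inhibitor of NF-kappaB signalling (0.53 ± 0.10), SAMSN1 (0.45 ± 0.10) and AHNAK (0.41 ± 0.12). CFLAR, an inhibitor of caspase-8 (0.41 ± 0.06), NFKBIA (0.37 ± 0.08), the chemokine receptor CXCR4 (0.36 ± 0.09) and PELI1 (0.35 ± 0.06) followed. The largest negative slopes were those of CTHRC1 (-0.66 ± 0.17), TGFBR2 (-0.38 ± 0.09), CCSAP (-0.37 ± 0.10), GGH (-0.36 ± 0.08) and ADA2 (-0.32 ± 0.08). CAMK2D (-0.31 ± 0.08), TMEM184B (-0.30 ± 0.06), ATRN (-0.26 ± 0.06), B9D1 (-0.25 ± 0.06) and MAPKAPK2 (-0.23 ± 0.06) came next. At least 1 other probe set of AHNAK, CFLAR, TGFBR2, CAMK2D, ATRN and B9D1 correlated below 0.5 with the one used.

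NF-kappaB targets rose with NR3C1. Of 13 members, 7 rose and none fell: TNFAIP3, CFLAR, NFKBIA, NFKB2 (0.31 ± 0.07), RELB (0.23 ± 0.06), TNIP1 (0.21 ± 0.04) and NFKB1 (0.16 ± 0.03); adjusted over the list alone, 9 rose. The list passed camera with the preset correlation (adjusted p = 1.56e-13) and with an estimated one (adjusted p = 0.000709). Its score rose with NR3C1 (r = 0.424, rho = 0.414, permutation p = 1e-05 for both, the smallest possible, adjusted p = 0.00018 and 0.00025; r = 0.428 without the 2 patients farthest from the median). In patients with the lower and the higher RNA integrity ratios, 72 each, rho was 0.438 and 0.398 (p = 0.00035 and 0.0009).

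Of 28 proliferation genes, CDC20 (-0.30 ± 0.08) and AURKA (-0.28 ± 0.07) fell with NR3C1, and adjusted over the list alone 13 fell; all 28 slopes were negative. This list passed camera with the preset correlation (adjusted p = 2.71e-10) and not with an estimated one (adjusted p = 0.472). Within the lower component of the proliferation score, NR3C1 and the score had r = -0.224 (p = 0.03) and rho = -0.270 (p = 0.0086), and r = -0.250 without the 2 patients farthest from the median; within the upper, r = -0.189 (p = 0.19), rho = -0.299 (p = 0.034) and r = -0.114. Of 12 glucocorticoid-responsive genes, CXCR4 rose and the others did not pass; adjusted over the list alone, 2 rose, and the score of the list showed no relation to NR3C1 that passed the test (r = -0.0296, p = 0.72; rho = -0.0618, p = 0.46). BCL2 (0.23 ± 0.06), IFIH1 (0.34 ± 0.07), VEGFA (0.27 ± 0.08) and TRIM33 (0.24 ± 0.06) rose, and JCHAIN (-0.32 ± 0.09), PSMB6 (-0.18 ± 0.04) and CD3E (-0.22 ± 0.06) fell.

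Scores of erythroid (r = -0.215, p = 0.0098; rho = -0.226, p = 0.0071, adjusted p = 0.045; r = -0.242 without the 2 patients farthest from the median), granulocyte (r = -0.210, p = 0.012; rho = -0.228, p = 0.0062, adjusted p = 0.045; r = -0.187 without them) and platelet markers (r = -0.209, p = 0.012; rho = -0.243, p = 0.0034, adjusted p = 0.031; r = -0.190) were lower where NR3C1 was higher. The adjusted p-values of their Pearson correlations, over 74 relations, were 0.056, 0.058 and 0.058. These relations are fragile: rho lost the threshold in 8 of 14 alternatives for erythroid, 7 of 14 for granulocyte and 6 of 15 for platelet markers. For cancer-testis antigens the Pearson correlation alone passed (r = -0.225, p = 0.0067, adjusted p = 0.041; rho = -0.187, p = 0.025, adjusted p = 0.11; r = -0.239 without the 2 patients). In camera, granulocyte markers and cancer-testis antigens passed with the preset correlation (adjusted p = 0.0248 for both) and not with an estimated one (0.472 for both). No list score followed the RNA integrity ratio after adjustment. Among lists not split into components, its largest values of rho were those with NF-kappaB targets (rho = -0.177, p = 0.034, adjusted p = 0.11, with r = -0.119, p = 0.15) and B cell markers (rho = 0.176, p = 0.035, adjusted p = 0.11, with r = 0.0916, p = 0.28). In the 17 patients of the upper component of monocyte and macrophage markers, rho was 0.370 (permutation p = 0.15). Without the 10% of patients with the highest ratio, the number of genes following NR3C1 was 80 positive and 48 negative.

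The 8 chromosomes that hyperdiploid myeloma tends to gain (3, 5, 7, 9, 11, 15, 19 and 21) varied together in mean expression. The mean Spearman correlation among them was 0.183 and that among all other pairs of autosomes was -0.0455, a difference of 0.229 (exact test over 319770 choices, p = 0.00188, one-sided). Chromosome 15 had the highest mean correlation with the other members of the set (0.301), followed by chromosomes 5 (0.225) and 19 (0.221), and chromosome 21 the lowest (0.0324). Among the other autosomes, chromosome 13 alone had a positive mean correlation with the 8 (0.0538), and chromosome 1 had the lowest (-0.352). Each patient was centred over all genes, so that negative correlations between the chromosomes of the set and the others arise in part by construction. The other pairs join these with the pairs among the autosomes outside the set. Those autosomes also had positive mean correlations with each other, from 0.0474 for chromosome 22 to 0.273 for chromosome 12, except chromosome 13 (-0.151). The comparison does not show that the 8 alone vary together. Genes on the long arm of chromosome 1 varied together: the mean correlation over pairs of 608 genes was 0.0827, against a median of 0.00827 for random lists (p = 0.0005, the smallest 2000 lists can give). The same held for all 22 autosomes (adjusted p = 0.001, the smallest 1000 lists can give), with chromosome 13 at the highest value (0.109), followed by chromosomes 14 (0.0726) and 15 (0.0695).

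**Figure D4:**
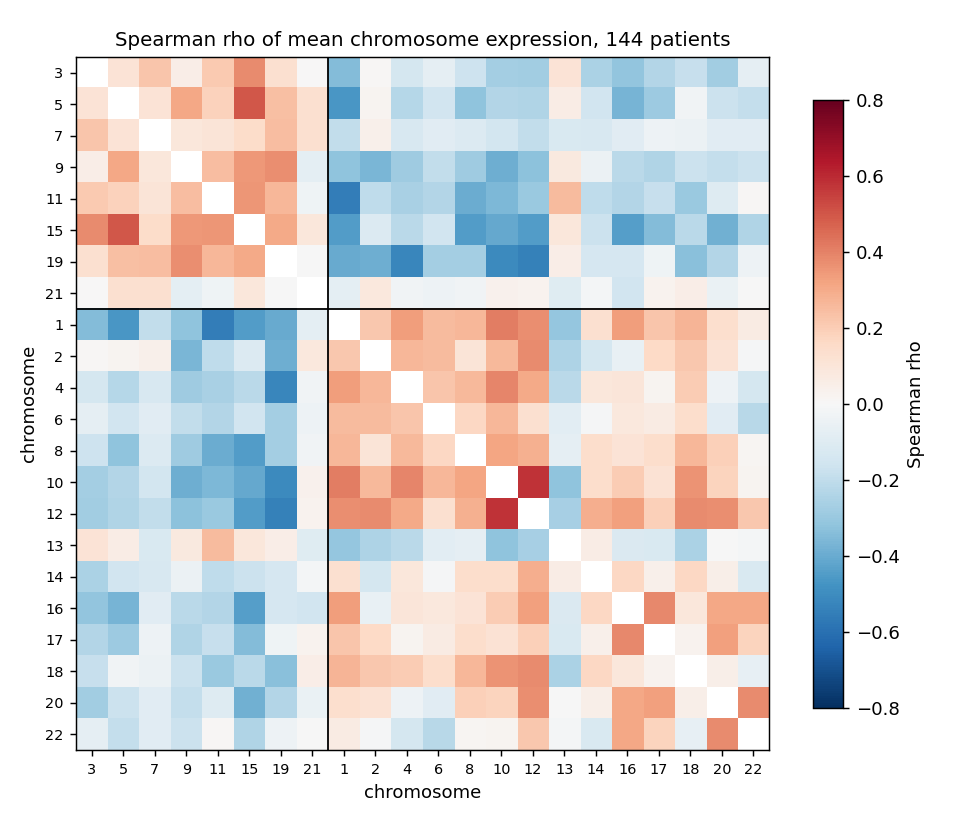
Spearman correlation of mean expression between autosomes over 144 patients (colour scale), with the 8 chromosomes of the hyperdiploid set first; black lines separate them from the other autosomes. The block of the 8 has a mean of 0.183, and chromosome 21 shows the weakest relation to it (0.0324).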

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

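Alternatives that split patients by components of the proliferation score, kept all columns as deposited, left out patients with doubtful B arrays or used the hybridisation controls as a covariate were chosen after seeing the data. The agreement of the arrays (median r 0.504 to 0.716 over 6 alternatives), the number of lists that vary together (14 to 22 over 13), the number of translocation targets and D cyclins high in at least 6 patients (6 to 8 over 10), the difference for the 8 chromosomes (0.218 to 0.245 over 14, highest p 0.00312) and the co-variation on 1q (0.0698 to 0.110 over 14) kept direction and threshold. Filter alternatives for high expression were not run, since that result uses all genes. No paired analysis was possible because there is 1 group.

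Counts of genes moved by over 1.5 times in some settings. Genes with a spread over 2 errors numbered 5858 with the lower 50% of genes left out and 6466 on array A. Fewer genes were counted there, and the share was also lower (67.0% and 72.2%, against 76.8%). As deposited, 4388 genes had such a spread. Genes following proliferation numbered 506 (361 positive, 145 negative) in the 72 patients with the lower 3 prime to 5 prime ratios. They numbered 439 (329 and 110) in the 72 with the higher ratios. Within the lower and upper component of the proliferation score they numbered 199 (172 and 27) and 150 (127 and 23). Fewer patients do not account for the drop in the lower component, which has 94; the score spans a narrower range within components and slopes are per SD within them, with a median of 41.2% and 72.9% of the slope over all patients. The cause was not tested further. Of the 257 genes called on NR3C1, 100% kept their sign in the parts with the lower and with the higher ratios. They had been chosen over the same patients, which made this likely in advance. Genes following NR3C1 numbered 21 (16 and 5) and 8 (8 and 0, with limma) in these parts. They numbered 128 (80 and 48) without the 10% of patients with the highest ratio, and 492 (258 and 234) with the mean over all probe sets; the cause was not tested. Of the 4 list relations with NR3C1, 1 remained past the threshold after quantile normalization, without the 10% of patients with the highest ratio and in each part by RNA integrity. It was 2 with the lower 50% of genes left out, without the 2 patients farthest from the median and without doubtful B arrays. The relation with NF-kappaB targets passed in all 16 alternatives (rho 0.398 to 0.506).

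Slopes on proliferation changed sign within the lower component, with adjusted p from 0.63 to 1, for CCND2 (-0.03944), STAP1 (0.1606), DNAJB9 (0.02833), HERPUD1 (0.001884), PSMB3 (-0.02802), PSMD11 (-0.008113), RPS6 (0.02677), ATP5F1A (0.03683), ILF2 (-0.01923), UBAP2L (-0.03405), SNAPIN (-0.06231), OPN3 (-0.001633), LAS1L (-0.04684) and GATA1 (-0.06418), and within the upper for TAGLN2 (-0.05315). The mean slope of plasma cell identity (0.03646), proteasome (-0.001502) and 1q21 genes (-0.01404) did so in the lower component; the cause was not tested. Over the other alternatives for single genes, 1652 values kept sign and threshold and 401 lost the threshold. The threshold was lost in 11 of 18 alternatives by GNG10 and in 9 of 18 by KLF6 on proliferation, and in 8 of 16 by JCHAIN on NR3C1.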

Other observations

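The measure of slopes kept under a covariate, the tests within components of the 8 chromosomes, with and without covariates, and the test of 1q genes were chosen only after the result was seen; the hybridisation controls were added as a covariate after the data were examined.

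The mean expression of genes on chromosomes 3, 5, 7, 9, 11, 15, 19 and 21 fell into 2 components of 71 and 73 patients, 2.97 SD apart, when list members were left out (4616 genes). Interferon response genes also formed 2 components, of 88 and 56 patients, 2.07 SD apart, and monocyte and macrophage markers formed components of 127 and 17 patients. For interferon genes the gain over 1 component was small (5.26 in the Bayesian information criterion). Each patient was centred over all genes, so lists outside the 8 chromosomes fall with their mean in part by construction. The permutation tests below do not allow for this, and so do not separate a fall from that effect. Within the upper component of the 8 chromosomes, endoplasmic reticulum chaperones on other chromosomes were lower where the mean of the 8 was higher (r = -0.339, permutation p = 0.0032; rho = -0.383, p = 0.00089, adjusted p = 0.009 over 24 lists in each component; r = -0.343 without the 2 patients farthest from the median). The same held for glucocorticoid-responsive genes (r = -0.316, p = 0.006; rho = -0.382, p = 0.00094, adjusted p = 0.009; r = -0.309) and for 1q21 genes (r = -0.385, p = 0.00069; rho = -0.393, p = 0.0006, adjusted p = 0.009; r = -0.406). In the lower component none of these passed the test (rho = -0.155, -0.0493 and 0.115), and the difference between components was not tested. Chromosome 1 as a whole had a mean correlation of -0.352 with the 8 over all patients. The relation of 1q21 genes cannot be told apart from that of their chromosome. Some markers of other cells fell with the mean of the 8 as well, although these scores rest on few genes outside the 8 chromosomes. The 4 platelet and megakaryocyte markers fell in the upper component (r = -0.297, permutation p = 0.01, rho = -0.333, p = 0.0038, adjusted p = 0.03, and r = -0.270 without the 2 patients farthest from the median). The 5 B cell markers fell in the lower (r = -0.436, p = 9e-05, rho = -0.411, p = 0.00032, adjusted p = 0.0077, and r = -0.386 without those patients).

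That ribosomal protein genes follow the 8 chromosomes even where they lie elsewhere is a hypothesis; its test was first written for all patients at once and was replaced by tests within components once these were seen. For the 10 measured ribosomal protein genes on other chromosomes, rho with the mean of the 8 was 0.426 in the upper component (73 patients, r = 0.401, permutation p = 0.00018 for rho, adjusted p = 0.0077; r = 0.394 without the 2 patients farthest from the median). In the lower component it was 0.0709 (71 patients, p = 0.56). Within the upper component, 102% of rho remained with RNA integrity partialled out (p = 0.00015, 95% bootstrap interval 79.1 to 117%) and 106% with hybridisation controls (p = 8e-05, 85.4 to 147%), which argues against both as the whole cause. With blood cell and platelet markers 86.5% remained (p = 0.0015, 48.5 to 119%); this interval reaches below the bound of 50%, so a part of other cells stays open, as does the lower component.

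Genes on 1q outside the 1q21 list may rise with proliferation. The 597 genes had a mean slope of 0.083, against 0.012 for other genes, and camera with an estimated correlation gave an unadjusted p = 0.00746, which was 0.00818, 0.00997 and 0.00735 with RNA integrity, blood cell markers and hybridisation controls as covariates. Over the 24 chromosome sets tested, the adjusted p was 0.179, so the test leaves the relation uncertain. Within the lower component of the proliferation score the mean slope was 0.034 against 0.022 (p = 0.652) and within the upper 0.031 against -0.015 (p = 0.172), which neither shows nor excludes it there. A second hypothesis, that genes of chromosome 13 fall as proliferation rises, was left undecided by the same test (p = 0.597, mean slope -0.0055 against 0.015).

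The genes following proliferation could reflect RNA integrity, other cells in the samples or array scaling and yield. Of the 1447 genes, 100% remained past the threshold with the same sign when the RNA integrity ratio was a covariate, 80.6% with the 5 blood cell marker scores and 97.7% with the hybridisation controls, all above the bound set before these shares were seen. These values argue against RNA integrity, the cells covered by the 5 marker lists, and array scaling and yield, each as the whole cause. After quantile normalization, 74.2% of the 1443 genes still tested kept sign and threshold. Platelet and megakaryocyte markers, which rose with proliferation in its lower component, were not among the covariates, so their part was not tested. No biological explanation was tested, since the labels give 1 group.

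For the genes following NR3C1, 100% of 257 remained with the hybridisation controls as covariate. This argues against array scaling and yield as the whole cause, as far as these controls measure them. After quantile normalization, 74.3% of the 257 kept sign and threshold. With RNA integrity 64.2% remained and with blood cell markers 58.4%, between the bounds set before they were seen, which left both undecided; a criterion on the slopes was added after these shares were seen. Slopes hardly moved: the median absolute slope was 0.21 before (median SE 0.054), 0.20 with RNA integrity (0.055) and 0.19 with blood cell markers (0.056). The genes that lost the threshold were not examined apart from the others. Each gene kept on the median 96.9% and 94.7% of its slope, with lower quartiles of 90.8% and 85.4%, which argues against either as the whole cause. A contribution to single genes stays open, and no biological explanation was tested. Platelet and megakaryocyte markers were not among the covariates.

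For the 8 chromosomes, 100% of the difference in mean correlation remained with RNA integrity as a covariate (exact p = 0.0019), 103% with blood cell markers (p = 0.00101) and 99.5% with hybridisation controls (p = 0.0018). These values argue against the 3 technical explanations, with other cells limited to the 5 marker lists, which leave out platelets and megakaryocytes. Shared extra copies of these chromosomes are a hypothesis that would need copy number data, which were not analysed here.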
